A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

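Spo11 oligos from SK1 diploids carrying tagged SPO11 were sequenced by pyrosequencing. Per the labels, cells grew at 30 °C for 14 h in presporulation medium from an optical density of 0.2 and then spent 4 h in sporulation medium. Spo11 complexes were precipitated and size-separated, the protein was digested, and the oligos were tailed with G, ligated to linkers and amplified. Culture 1 gave 3 datasets: A, B by a second PCR from the ligated oligos of A, and C by a separate ligation of the same oligos. Culture 2 gave 1 dataset.

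Both files cover all 4 datasets together. The first lists uniquely mapped reads with start, end, name, strand and a score, and the authors' score is one number per read from the mapping. For 53.3% of reads this score lay within 0.01 of a function of read length alone with a genome of 12 Mb, and 35.8% lay below it and 10.9% above; the score was not used as a filter. The second is a map that the authors call curated and holds raw hit counts per position with both strands together, per the file headers. What the curation did, the aligner and the genome build are not given in the sources used here; the file headers name S288C. The map held 2026265 hits at 463043 positions, and 98.4% of the positions in either file had the same count in both. Comparisons rest on the list, and the curated map was an alternative. The deposited score and counts carry no stated normalisation.

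Reads were assigned to 4 sequencing runs by the first 7 characters of the read name. No label ties a run to a dataset, so runs are given as single values or ranges and never as replicates, and no run was assigned to a culture. The depth was 395612 to 587674 reads per run. No molecular identifiers mark PCR copies, so intervals and floors cover counting error only. The floor for a count of 0 was taken as 3 counts and intervals are 95% Wilson or exact Poisson intervals.

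The 5′ end was the listed start for top-strand reads and the listed end for bottom-strand reads. Hotspots were called from 5′ ends of both strands on 16 chromosomes, smoothed with a Hann window of 201 bp. Segments at or above 2.3 times the mean were kept, merged at gaps of 200 bp or less, and required to be at least 25 bp long with at least 10 RPM (oligos per 1000000 mapped oligos). The gene lists, the hotspot rule, the planned tests and the first set of alternatives were fixed before the data were examined. Tested on simulated data, the rule found 0% of 608 planted hotspots of 20 oligos, 6.21% of 596 of 50 and 100% of 587 of 100, and 0 of 1836 calls had no planted hotspot. The simulated background was even and too sparse to reach the threshold, so the absence of false calls was fixed in advance. All planted hotspots had the same spread, and the simulated total was below the real one. The shares found hold for that setting only, and real hotspots of as few as 21 oligos were called. A planned comparison with 100 maps of uniformly placed oligos gave 0 hotspots, which the depth and window fix in advance, so nothing rests on it. The simulated strand offset of 2 was found, but it was planted without scatter, so this was fixed in advance and nothing rests on it. A planted list effect was called in 91 of 100 simulations, and a list without effect had p under 0.05 in 4 of 100. The 91 of 100 holds only for the list size and effect that were planted. Both were close to those reported for cytosolic ribosomal protein genes, so this share is not independent of that result. The planted list was judged by p multiplied by the number of lists, not by the Benjamini-Hochberg adjustment used for the reported lists. The 91 of 100 does not give the power for smaller lists or weaker effects, so a list that did not pass may still differ.

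Genes and gaps came from a table of 6002 protein-coding genes of the current S288C reference, used for names and orientation only. The register of map and table was checked in 204 windows of 50 kb on 15 chromosomes. The shift taken was the one at which genes held the fewest oligos, with at most 10 counted per position. In 203 windows (99.5%) the shift was within 100 bp, with a median of −5 bp. On chromosome XI the median was 5 bp in 3 windows before 200 kb and −375 bp in 9 windows after, so XI was left out of all gene naming. Each hotspot summit was given to the gap it lay in or the nearest one: of 3409 hotspots on the 15 chromosomes, 91.1% lay in a gap, and 217 on XI stayed unnamed. Moving the table by 100 bp changed the gap of 1.41% and 0.880% of hotspots.

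The planned measure, oligos per kb in the 500 bp upstream of each gene, needs gene coordinates in the build of the map. It was replaced by the gap on the 5′ side of each gene, scored as holding a hotspot or not, with two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over 3 pairs of gap classes and over 15 lists. Genes of a list can share a gap, so they are not fully independent. Ribosomal protein genes were picked by symbol, which also took in RPP1, a subunit of RNase P; without it 76 of 132 members had a hotspot (difference −16.6 points, exact adjusted p = 0.000743). Chromosome length and density were compared by Pearson and Spearman correlation with two-sided permutation tests (100000 resamples), chromosome ends by an exact two-sided sign-flip permutation test over 16 chromosomes, and strand offsets by products of counts at offsets of −50 to 50. Since the files used here pool both cultures, no p-value measures variation between cultures.

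Genes named in the text followed a rule: the genes flanking the 10 hotspots with the most oligos, the 2 highest and 2 lowest members of each list by oligos in the 5′ gap (ties by systematic name), all known hotspot genes, all loci altered in the strain, the densest and sparsest chromosomes, and the 3 longest stretches without an oligo. LYS1, PRO2, chromosomes I, III and XII, single chromosome ends, HXT6, TAR1 and genes in the closing section were named after their values were seen.

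Several planned analyses were not run. Agreement between datasets and leaving out each dataset need values per dataset, which pooled files do not give; runs were left out instead. Base composition, the intergenic share, centromere density, transfer RNA and small nucleolar RNA genes, retrotransposons and ribosomal DNA need a genome or annotation in the build of the map, which was not used here. Loci altered in the strain were read from their 5′ gaps only. Mapping to S288C leaves out sequence that only SK1 has and sequence that is repeated, such as chromosome ends and gene copies. Conversely, S288C sequence that SK1 lacks would appear empty of oligos.

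Alternatives changed the window, threshold, merging, copy limit, strand, run, source file, terminal length, gap length, pseudocount, test, gene table position and set of genes. Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots by matplotlib 3.10.9.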

Results

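Meiotic recombination begins when Spo11 cuts both strands of a chromosome and stays bound to the DNA ends, from which it is released with a short oligo attached. Sequencing these Spo11 oligos maps the breaks, because the 5′ end of each oligo marks the cut. The series covers diploid budding yeast of the SK1 background at 4 h in sporulation medium. Culture 1 gave 3 technical datasets (A, B and C) and culture 2, grown separately, gave 1. Both files pool the 4 datasets, so the cultures were not compared. The read list held 2024944 uniquely mapped oligos at 515423 distinct positions and strands, 49.9% of them on the top strand. Read names show 4 sequencing runs, which no label ties to a dataset: E8YXO9P with 395612 reads, FE8RWPF with 587674, FFA0GWK with 566308 and FIDXMPL with 475350. Across hotspots (not independent replicates), oligo counts of FIDXMPL correlated with the other runs at 0.941 to 0.948, against 0.989 to 0.992 among those 3. Values per run are given as ranges, intervals cover counting error only, and no estimate of the spread between cultures was possible.

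Uniquely mapped Spo11 oligos were mostly 25 to 32 nt long, with smaller shares of shorter and longer ones. The bounds of the length classes were set for counting. The commonest length was 29 nt and the mean 30.5 ± 6.27 nt (SD over 2024944 reads, range 12 to 76 nt). Lengths count the listed start as the first base of the read, which the file does not settle. Otherwise every length and class bound is a base too long. Oligos of 25 to 32 nt made up 59.9% of reads (95% Wilson interval 59.82 to 59.95%). Those of 12 to 24 nt made up 11.7%, those of 33 to 40 nt 21.5%, and those of 41 to 76 nt 7.0% (6.97 to 7.04%). The share of 41 to 76 nt was 3.26% in run FFA0GWK and 7.74 to 9.27% in the other runs. That of 12 to 24 nt was 16.6% in FFA0GWK and 8.42 to 10.4% in the other runs. The labels state that PCR products were selected on a gel, and only uniquely mapped reads are listed. These shares therefore describe sequenced products that mapped uniquely. Very short reads can match several places, so the share of short oligos may be too low.

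Oligo ends on opposite strands lay at a fixed spacing, the trace that staggered cutting of both strands by Spo11 leaves. Products of top-strand and bottom-strand counts were highest where the bottom-strand end lay 2 positions to the right of the top-strand end in the coordinates of the file, 6.71 times the median over offsets of −50 to 50. This offset was the best on 16 of 16 chromosomes (6.4 ± 2.5 times the median, SD, n = 16) and in 4 of 4 runs (5.69 to 7.30 times). Counting each position and strand once lowered the peak to 1.75 times. The overhang is 2 or 3 bases depending on whether the listed start is the first base of the read, and the file does not settle that. Reads of 25 to 32 nt with identical intervals on opposite strands were 2.39 times as frequent as those with intervals shifted by 6 to 15 positions.

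**Figure D1:**
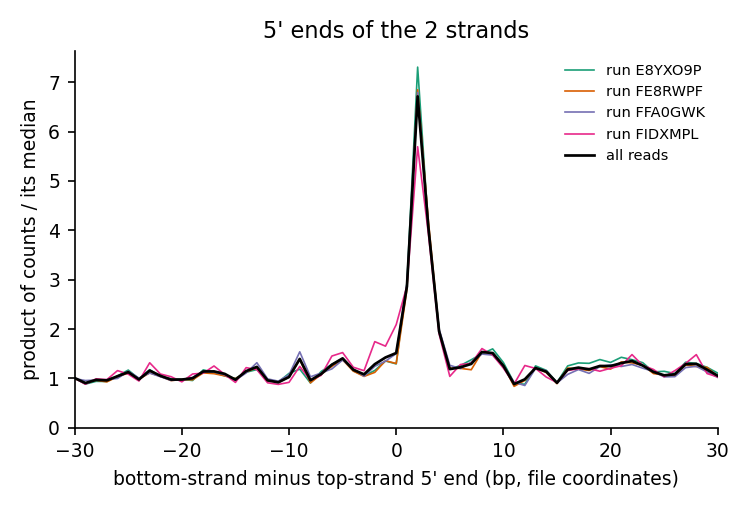
Product of top-strand and bottom-strand 5′ end counts, relative to the median over all offsets, against the offset of the bottom strand from −30 to 30 bp; the thick line is all reads and thin lines are the 4 runs. The pooled peak is 6.71 at offset 2, and the runs peak there at 5.69 to 7.30.

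Most oligos lay in 3626 hotspots, which covered 8.20% of 12 Mb and held 88.8% of them (1798127 oligos, 95% Wilson interval 88.8 to 88.8%). The median hotspot was 211 bp wide (10th to 90th percentile 98 to 527 bp) and held 241 oligos, with neighbouring summits a median of 2455 bp apart. Counts ranged from 21 to 10255 oligos, and the strongest hotspot held 42.6 times the median. The 538 strongest hotspots held 50% of all mapped oligos, and the top 100 held 19.4%. Runs taken alone gave 3661 to 3747 hotspots, of which 93.0 to 94.8% overlapped a pooled one. The pooled reads include each run, so this overlap is partly built in and does not measure reproducibility between runs.

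The strongest hotspot lay on chromosome VI (95089 to 96288) between FRS2, a phenylalanyl-tRNA synthetase subunit, and GAT1, a GATA activator of nitrogen genes. It held 10255 oligos (95% Poisson interval 10058 to 10455), 5064 RPM (oligos per 1000000 mapped oligos), and 4637 to 5447 RPM in the runs. Next came the gap between SND1 and CCT6, a chaperonin subunit (IV, 835505 to 836384), with 8332 oligos, and the 5′ side of ERG1, the squalene epoxidase of sterol synthesis, beside ATF2 (VII, 848469 to 849091), with 7886. The bottom-strand position VII 848758, beside ERG1, was the most hit single position with 1915 oligos. YMR265C and RSN1 flanked the fourth hotspot (XIII, 797888 to 798520), with 7804 oligos. SRB2, a Mediator subunit, and NCP1, the reductase that serves cytochrome P450 enzymes, flanked 7588 oligos (VIII, 189513 to 190515). The telomerase subunit gene EST3 and the fatty acid activation gene FAA3 flanked 7033 oligos (IX, 337549 to 339340). The sporulation septin gene SPR3 and the sterol synthesis gene ERG25 flanked 6590 (VII, 609290 to 610481). LEU4, which starts leucine synthesis, and MET4, activator of sulfur amino acid genes, flanked 6434 (XIV, 426823 to 427591). YIL012W and the cell wall gene TIR3 flanked 5907 (IX, 332520 to 333758), and the clathrin adaptor gene YAP1801 and the mitochondrial pyruvate carrier gene MPC2 flanked 5900 (VIII, 422436 to 422949). Of these 10 hotspots, 7 lay between divergent genes and 3 between tandem genes.

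Hotspots lay mostly in gaps that hold the 5′ end of a gene. On 15 chromosomes, 1176 of 1447 gaps between divergent genes (81.3%, 95% Wilson interval 79.2 to 83.2%) held a hotspot (the nearest gap counts for the few summits inside genes), as did 1756 of 2671 gaps between tandem genes (65.7%, 63.9 to 67.5%). Convergent gaps, which lie between 2 gene ends, held one in 127 of 1434 cases (8.86%, 7.49 to 10.4%). Where a hotspot was present, the median count per gap was 182 RPM in divergent, 117 in tandem and 60.7 in convergent gaps. Divergent gaps held 50.5% of hotspot oligos, tandem gaps 47.3% and convergent gaps 2.12%. Runs taken alone gave 80.2 to 82.9%, 66.2 to 67.3% and 9.21 to 10.5% of gaps. Divergent exceeded tandem gaps by 15.5 points (two-sided Fisher's exact test, adjusted p = 7.92e-27 over 3 pairs), tandem exceeded convergent by 56.9 points (adjusted p = 2.40e-299), and divergent exceeded convergent by 72.4 points (−log10 p of 373). Counting each position and strand once lowered the first difference to 8.76 points (Fisher's exact test, adjusted p = 1.48e-13). Median gap length ranged from 230 bp in convergent to 506 bp in divergent gaps, and among gaps within one range of lengths divergent exceeded tandem by 19.0 points and tandem exceeded convergent by 57.4. Gaps are not independent replicates.

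**Figure D2:**
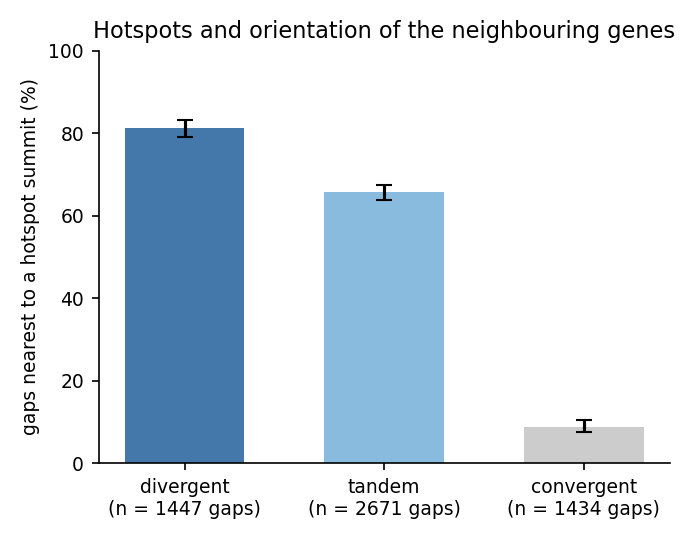
Share of gaps between neighbouring genes that held a hotspot (percent, bars start at 0), by the orientation of the flanking genes; error bars are 95% Wilson intervals and n is the number of gaps. Divergent gaps reach 81.3%, tandem gaps 65.7% and convergent gaps 8.86%.

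Of 15 gene lists, genes of amino acid biosynthesis had a hotspot on their 5′ side more often than other genes, and cytosolic ribosomal protein and hexose transporter genes less often. Among 61 amino acid biosynthesis genes, 57 had one (93.4%, 95% Wilson interval 84.3 to 97.4%, others 73.6%; two-sided Fisher's exact test, adjusted p = 0.00133). LEU4 (3177 RPM in its 5′ gap) and ARG1, of arginine synthesis (1897), led this list, while TRP4, HIS6, LYS1 and PRO2 had no hotspot there. Cytosolic ribosomal protein genes had one in 76 of 133 cases (57.1%, 48.6 to 65.2%, others 74.2%; exact adjusted p = 0.000350), and the difference shrank to −9.30 points with each position and strand counted once (exact adjusted p = 0.0316). RPL43A (1264 RPM) and RPL7B (985) were highest, and RPS8A and RPL19A had none. Most of these genes exist as similar pairs, and members with a second copy had a hotspot in 55.8% of 113 cases against 68.4% of 19 without one. Hexose transporter genes had one in 8 of 19 cases (42.1%, 23.1 to 63.7%, others 73.9%; exact adjusted p = 0.0168). The glucose sensor gene RGT2 (1041 RPM) and HXT2 (483) were highest, while HXT15 and HXT7 had none, and reads shared by near-identical copies such as HXT6 and HXT7 cannot map uniquely. The hexose transporter call was lost among the 15 members over 20 kb from a chromosome end (difference −22.7 points, exact adjusted p = 0.313) and with 5 other settings. No other list passed even the unadjusted threshold, among 5565 genes tested.

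**Figure D3:**
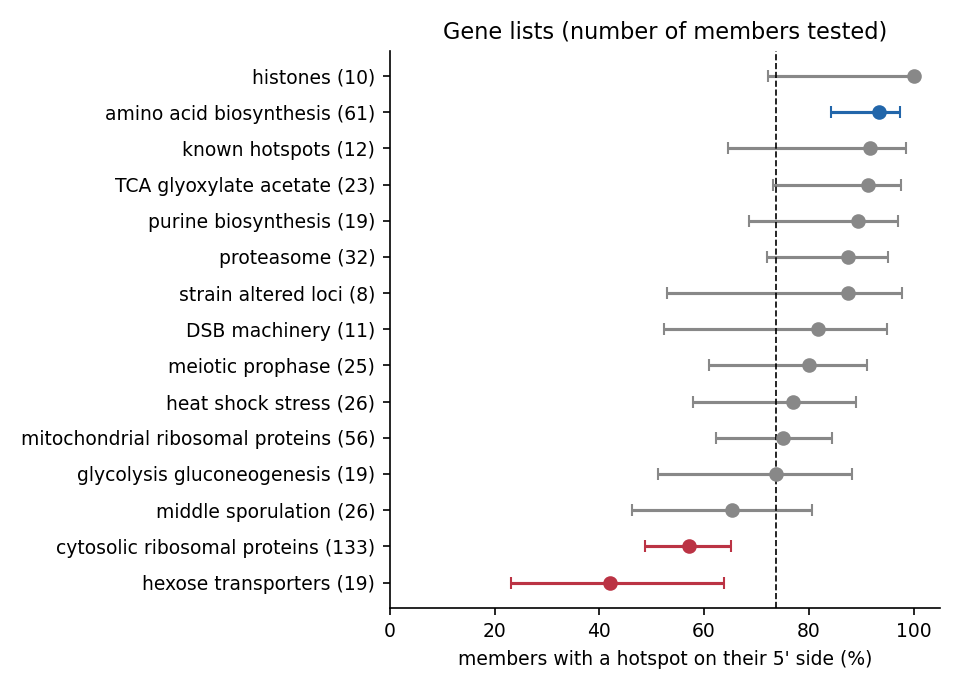
Share of genes with a hotspot in the gap on their 5′ side (percent) for each of 15 gene lists, with the number of genes in brackets; error bars are 95% Wilson intervals and the dashed line is the share among other genes, with lists that passed the test coloured. Amino acid biosynthesis lies at 93.4%, cytosolic ribosomal proteins at 57.1% and hexose transporters at 42.1%.

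Genes of meiosis itself did not pass the test. Genes of the break machinery had a hotspot in 9 of 11 cases, with RAD50 at 157 and SAE2 at 126 RPM and none at XRS2 or REC102 (adjusted p = 0.923, Fisher's exact test as for all lists). Meiotic prophase genes had one in 20 of 25 cases, led by MSH4 (735) and ZIP1 (400.5), with none at DMC1 or HOP2 (exact adjusted p = 0.923). Middle sporulation genes had one in 17 of 26 cases, led by CDA2 (1350) and CLB5 (940), with none at the divergent pair DIT1 and DIT2 (exact adjusted p = 0.617). Histone genes had one in 10 of 10 cases, from 489 RPM at HHO1 and 244 at HHF2 to 16.8 in the gap shared by HTA1 and HTB1 (exact adjusted p = 0.218).

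Among metabolic lists that did not pass, the TCA cycle and acetate list had a hotspot in 21 of 23 cases, led by ACH1 (1315 RPM) and FUM1 (1090), with none at LSC2 or CIT3 (exact adjusted p = 0.218). Purine synthesis genes had one in 17 of 19 cases, led by GUA1 (1124) and IMD3 (841), with none at PRS4 or ADE16 (exact adjusted p = 0.382). Glycolysis and gluconeogenesis genes had one in 14 of 19 cases, led by PFK2 (1294) and CDC19 (1117), with none at PGI1 or TDH3 (exact adjusted p = 1). Proteasome genes had one in 28 of 32 cases, led by PUP3 (691) and RPN6 (674), with none at RPT2 or RPN10 (exact adjusted p = 0.261). Heat shock genes had one in 20 of 26 cases, led by TPS1 (890) and SSA1 (673), with none at SSA3 or HSP30 (exact adjusted p = 0.953). Mitochondrial ribosomal protein genes had one in 42 of 56 cases, led by RSM7 (1653) and MRPL8 (1609), with none at MRPL32 or MRPL1 (exact adjusted p = 1).

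Genes long studied as recombination hotspots had one in 11 of 12 cases (exact adjusted p = 0.382), and this list is not independent evidence, since its members were chosen for their breaks. GAT1 and CCT6 flanked the strongest and second strongest hotspots. BUD23 and ARE1 flanked the 13th (III, 211566 to 212426, 5675 oligos). CYS3, of cysteine synthesis, had 1755 RPM on its 5′ side (rank 43) and its neighbour DEP1 1141. ARG4 had 882, DED81 663, HIS2 452 and THR4 265. HIS4 had 84.0 and FUS1 no hotspot. At loci that the labels list as altered in the strain, 7 of 8 genes had a hotspot (exact adjusted p = 0.923): ARG4, LYS2 (758), LEU2 (743), HO (246), HIS4, URA3 (70.6) and SPO11 (47.9), with none at the deleted NUC1. The strain also carries LEU2 inserted at HIS4 and NUC1 and LYS2 inserted at HO, and the map, which follows S288C, places reads of every copy at the original gene.

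Short chromosomes received more breaks per kb. Chromosome VI had the highest density, 112 RPM per kb (runs 109 to 114), and chromosome I followed with 102. Chromosome XV had the lowest, 75.8 (74.5 to 77.9), with XII next at 75.9, a 1.48-fold range around the mean of 83.2. Chromosome III was low for its 316 kb, with 77.4 (71.7 to 79.8). Across 16 chromosomes density fell with length (Pearson r = −0.68, permutation p = 0.00307, adjusted p = 0.00921 over 3 relations; Spearman rho = −0.70, permutation p = 0.00325, adjusted p = 0.00975). Leaving out chromosomes I and IV, farthest from the median length, gave r = −0.62 (permutation p = 0.0112) and rho = −0.64 (permutation p = 0.0172). Among runs, r was −0.71, −0.72 and −0.74, and −0.48 in FIDXMPL (permutation p = 0.0580), where the relation passed no threshold. Neither the number of hotspots per 100 kb (r = −0.36, permutation p = 0.177, rho = −0.43, p = 0.0994) nor the median oligos per hotspot (r = −0.36, p = 0.170, rho = −0.33, p = 0.211) passed alone.

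**Figure D4:**
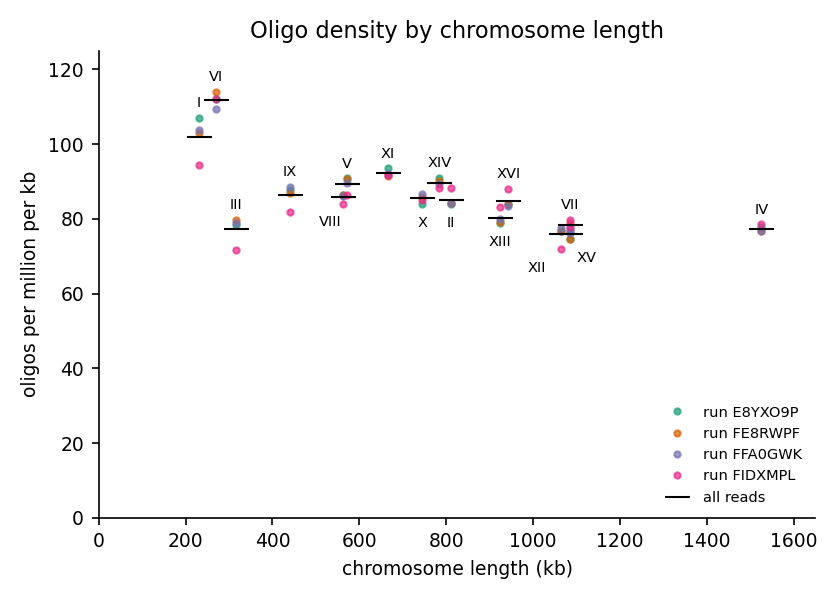
RPM per kb against chromosome length in kb for the 16 chromosomes; horizontal lines are all reads and points are the 4 runs. Density runs from 112 on VI to 75.8 on XV, and III lies low among short chromosomes at 77.4.

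Chromosome ends were poor in breaks. In the terminal 20 kb of both ends, density relative to the rest of the same chromosome was −3.08 ± 1.25 on the log2 scale (SD, n = 16), 8.48-fold lower, and lower on 16 of 16 chromosomes (exact sign-flip permutation p = 3.05e-05, the smallest it can give). Chromosome X was lowest at −6.38 and VI highest at −1.22. The left end of X had 0 oligos in 20 kb, which allows up to 3, and that of IX had 2, whereas the right end of VI had 3723. Over 32 ends, density was 11.3 ± 22.3 RPM per kb (SD) within 10 kb (median 3.48) and 17.7 from 10 to 20 kb. The next 4 bins of 10 kb had 60.9, 74.6, 99.5 and 74.5, so the rise was not steady. Runs gave means of −3.28 to −2.98, whereas counting each position and strand once gave −2.16. Repeated end sequences cannot map uniquely, so part of each end is not measured. End sequence of S288C that SK1 lacks would also hold no oligos, which was not checked.

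**Figure D5:**
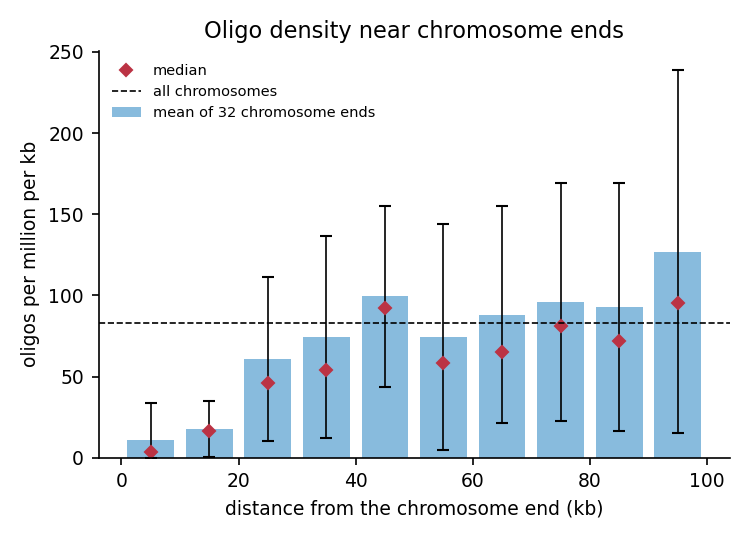
Mean RPM per kb over 32 chromosome ends against distance from the end in 10 kb bins, with medians as diamonds and the density of all chromosomes dashed; error bars are SD over ends, drawn down to 0 at most. Density is 11.3 in the outermost bin, 60.9 from 20 to 30 kb, 74.6 from 30 to 40 kb, 99.5 from 40 to 50 kb and 74.5 from 50 to 60 kb.

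The 3 longest stretches without a mapped oligo, outside chromosome ends, were on XII, IV and VII. The longest spanned 22.1 kb on XII (459805 to 481877), with the asparaginase genes ASP3-1 and ASP3-2. It also held the reading frames YLR154C-G and YLR154C-H and adjoined 8.42 kb with TAR1, a gene within the ribosomal DNA. Ribosomal DNA was not left out of this ranking, and part of the stretch may lie in that repeat. The next spanned 13.1 kb on IV (981133 to 994183), with retrotransposon open reading frames named YDR261, YDR262W and DIN7, and the curated map had 689 hits there. The third spanned 12.1 kb on VII (811382 to 823480), with retrotransposon reading frames named YGR161. On XII and VII, where the curated map also had 0 hits, a count of 0 allows up to 3 uniquely mapped oligos. On IV the 0 depends on the file used. Repeats among these sequences cannot map uniquely, and S288C sequence that SK1 lacks would also hold no reads. Whether SK1 carries these stretches was not checked.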

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

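Both the comparison by 10 kb windows and its minimum of 500 hits were chosen after the data were seen. The curated map holds 7804 hits at 2659 positions where the read list has no read, and 132 windows exceed the limit of 3 hits that a count of 0 allows. The 3 windows with 500 or more are given here.

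Each of these windows holds hits that the read list, on which the report's comparisons rest, does not have; the curated map served only as an alternative and for the stretches without oligos. On chromosome XVI, 860001 to 870000 had 1154 such hits at 136 positions, most between 860680 and 860901, where the gene table lists no protein-coding gene. On chromosome IV, 990001 to 1000000 had 689 hits at 81 positions, most between 992749 and 993050 beside YDR262W, inside a stretch where the list had 0 oligos. On chromosome VI, 110001 to 120000 had 524 hits at 114 positions, most between 114546 and 115067 beside AUA1 and WWM1. No explanation was tested.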

How the results depend on the processing

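The alternatives that leave out or isolate a run, use the curated map, move the gene table, keep summits inside gaps, test log2 hotspot oligos with pseudocount 1, drop RPP1 or chromosome III, and apply hotspot or strand settings to gene results, or single strands to chromosome ends, were chosen after the data were seen. Of 599 alternative values, 532 kept their direction and side of the threshold, moved within their spread or, for counts of hotspots and of lists, stayed within 1.5 times the reported count, 7 lost a call, 2 gained one, 34 changed direction and 24 moved.

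Hotspot numbers ranged from 2979 to 4427, the offset was 2 in 12 of 12 alternatives, and chromosome ends ranged from −3.95 (terminal 10 kb) to −1.31 (terminal 40 kb) with exact p = 3.05e-05 in 15 of 15. Divergent above tandem above convergent gaps held in all 25 alternatives for each pair. Amino acid biosynthesis (adjusted p 0.000196 to 0.0330) and cytosolic ribosomal proteins (3.27e-07 to 0.0420) were called in 27 of 27, and 2 to 4 lists were called. Correlation of length and density ranged from −0.83 without chromosome III to −0.48 in run FIDXMPL alone (p = 0.0580), which lost the call; 15 of 16 kept it.

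The share of oligos in hotspots, 88.8%, moved beyond its narrow counting interval in all 18 alternatives. It was 78.9% with each position once, 86.9% with at most 10 per position, 89.0% and 89.1% for the top and bottom strand, 89.3% and 87.8% with a narrower and a wider window, 91.5% and 83.1% at 1.5 and 4 times the mean, 88.4% without merging and 89.0% in the curated map. Without E8YXO9P, FE8RWPF, FFA0GWK and FIDXMPL it was 88.7%, 88.7%, 89.1% and 88.9%, and in each alone 90.03%, 89.9%, 88.7% and 89.2%. The median oligo length became 30 nt for the top strand, in hotspots, without FFA0GWK, and in E8YXO9P, FE8RWPF and FIDXMPL alone. The cause was not tested.

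Hexose transporters lost their call in 6 of 27 alternatives (adjusted p 0.00147 to 0.313 over all): −23.9 points with the wider window (0.182), −21.0 at 4 times the mean (0.277), −26.5 with the table moved by 100 bp (0.0780), −22.7 away from ends (0.313, fewer members), and medians of −6.45 and −9.76 with pseudocounts 1 and 0.1 (0.0617 each). The proteasome list gained a call with each position once (15.1 points, 0.0394) and known hotspots with pseudocount 10 (3.4, 0.000150). The cause was not tested.

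Reversed values occurred only in 7 lists without a call in the report, as differences in points unless medians are named. Break machinery gave −10.5 with the top strand, −11.4 with the wider window, −8.51 at 4 times, −1.27 without E8YXO9P, −1.62 in FE8RWPF, −10.2 in FFA0GWK, and medians of −0.53, −0.53 and −0.47 with pseudocounts 1, 0.1 and 10. Glycolysis gave 7.78 with the wider window, 10.7 at 4 times, 4.17 in E8YXO9P, 2.64 inside gaps, 1.40 within orientations, and medians of 1.14, 1.14 and 1.06. Proteasome gave −0.307 with the wider window, −13.1 at 4 times, and medians of −0.80, −0.81 and −0.70. Mitochondrial ribosomal proteins gave −1.15 at 1.5 times, −0.992 without FFA0GWK, −0.976 away from ends, and medians of −0.0516, −0.0522 and −0.0466. Meiotic prophase gave −1.94 with the wider window and −3.05 at 4 times, middle sporulation 3.14 without FIDXMPL and 2.60 in FE8RWPF, and heat shock −0.400 with each position once and −0.709 in FFA0GWK. The cause was not tested.

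Not run were leaving out each dataset, centromere windows, ribosomal DNA counted, dubious reading frames, other upstream windows, base composition, intergenic share, and transfer RNA, small nucleolar RNA and retrotransposon windows. No paired analysis was possible because the cultures share no replicate numbers and the files pool all datasets. The calling rule can miss weak hotspots: simulated ones of 50 oligos, all of the same spread, were found in 6.21% of cases. Real hotspots of as few as 21 oligos were called, so this share does not describe real hotspots of that count. What depth limits was not simulated, and single runs gave 3661 to 3747 hotspots against 3626 from all reads.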

Other observations

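Chosen after results were seen were the groups of sterol, nitrogen and iron genes, the comparison of runs, the tests of second gene copies, of equal read numbers, and of opposite-strand pairs of 41 to 76 nt.

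Genes of sterol synthesis stood beside strong hotspots. ERG1, NCP1, ERG25 and ERG11, all among the strongest 20 hotspots, prompted the group. Its other 20 members had a median of 391 RPM in the 5′ gap against 85.4 for other genes, a difference of 2.18 on the log2 scale (permutation p = 0.0210, adjusted p = 0.0334 over 3 groups). ERG2 (1860) and ERG3 (1628) were highest among these, and ERG26, ERG27 and ERG6 had no hotspot. This may be a property of the group, as a hypothesis found and tested on the same map. The share of members with a hotspot, 85.0% against 73.8%, did not pass (Fisher's exact p = 0.317).

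Iron uptake and related genes, chosen because runs differed there, had a median of 302 RPM over 21 members not seen before (permutation p = 0.0223, adjusted p = 0.0334). FET3 had 1965 and FTR1 1788. This iron group also took in genes that do not take up iron themselves, such as ISU1, ISU2, ATX1 and VMR1. The share of the 21 with a hotspot, 90.5% against 73.7%, did not pass (Fisher's exact p = 0.131). Nitrogen catabolism genes, prompted by GAT1, CAR1 and DUR12, had a median of 168 over 19 other members (permutation p = 0.185). MEP1 (1720) and CAR2 (2064) were high, and DAL7 and MEP2 had no hotspot. The bound written beforehand took a p of 0.05 or more as excluding a group effect, which was wrong, since the median lay above that of other genes and a missed threshold excludes nothing. That group stays open.

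Run FIDXMPL stood apart from the other 3 runs at many hotspots. Of 974 hotspots with 500 or more oligos, 34 differed more than 2-fold from the mean of the other runs in FIDXMPL, against 1, 0 and 0 in E8YXO9P, FE8RWPF and FFA0GWK. The hotspot of FIT3 and FRE5, of iron uptake, had 23.1 RPM in FIDXMPL and 288.2 to 332 in the others, and that of the siderophore transporter gene SIT1 had 202 against 1106 to 1231. Drops were not limited to iron genes: the hotspot of RPS4A and YJR146W had 177 against 1062 to 1197, a larger fold than at SIT1, and that of DIS3 and TAT2 had 236 against 788 to 968. Higher in FIDXMPL were SHM2 and REX2 (827 against 235 to 275) and YNL134C and FYV6 (776 against 179 to 267). At 19 hotspots of the iron group not seen before, the median log2 ratio of FIDXMPL to the mean of the others was −0.81. The ratio was below 0 at 17 of 19, and 0 of 10000 random sets had as low a median. The random sets were not matched for position. Several of the 19 lie near chromosome ends, such as that of ARN2 (VIII, 10646 to 11115). FIDXMPL was also the run lowest at chromosome ends (9.71-fold lower, 7.89 to 8.44-fold in the others). The hotspot of FIT2 (XV, 1058921 to 1059197) also lies close to that of FIT3 and FRE5, which prompted the group. The random sets therefore do not separate iron genes from position. In FIDXMPL, FET3 had 1022 against 2159 to 2299 and FTR1 1130 against 1919 to 2062. VMR1, not itself an uptake gene, had 27.3 against 207 to 258. The exceptions were ISU2 (1121 against 1006 to 1122) and ATX1 (44.2 against 27.8 to 57.9). ISU1, counted below 0, hardly differed (787 against 801 to 809).

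The difference of FIDXMPL was weighed against 3 technical explanations. At equal numbers of reads its lowest correlation with another run was 0.940, against at least 0.989 among the others, which argues against depth as the whole cause. With reads of 25 to 32 nt alone its highest correlation was 0.939 against at least 0.984, and with each position counted once 0.966 against at least 0.987, which argues against read lengths and against a few copied positions, although the last narrowed the gap. A difference between cultures and other differences in library preparation stay open, because no label ties a run to a culture.

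Cytosolic ribosomal protein genes had fewer 5′ hotspots. Compared within 5 classes of gap length inside each orientation, 76 members had a hotspot where 101.6 would by chance (−19.4 points, exact p = 2.26e-07), which argues against orientation and gap length as the cause. Loss of reads shared by gene copies may contribute: 68.4% of 19 members without a copy had a hotspot (95% Wilson interval 46.0 to 84.6%), a range that includes the 74.2% of other genes, against 55.8% of 113 with one (Fisher's exact p = 0.329). The few members without a copy keep this open, and no biological explanation was tested, since the design gives none.

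Reads on opposite strands often covered nearly the same interval. Identical intervals were 2.39 times as frequent as intervals shifted by 6 to 15 positions in reads of 25 to 32 nt (16 of 16 chromosomes, exact sign-flip permutation p = 3.05e-05, the smallest possible), consistent with some reads given the wrong strand. For 2 nearby breaks on one molecule, a shift of 3 is expected if the listed start is the first base and of 2 otherwise, which the file does not settle. In reads of 33 to 76 nt the ratio at 3 was 1.26, beside 1.27 at a shift of −12 (exact sign-flip p of the difference 0.853). The prediction written beforehand asked that 3 be the highest shift apart from 0, and counted another higher shift against paired breaks. By that rule it failed, though the 2 ratios could not be told apart. In reads of 41 to 76 nt, a class chosen afterwards, the ratio at 3 was 2.15 against 1.36 at the next highest shift, which is 2 (exact sign-flip p = 3.05e-05). Paired breaks may therefore explain part of the long class under the first reading only, and the explanation stays open.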
